A study of Mus musculus with 6 samples.

How the data were processed

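Whole-liver RNA was sequenced from mice with a floxed Acss2 gene (ACSS2-flox, the control) and from mice that lack ACSS2 in hepatocytes (ACSS2-HKO). ACSS2 is the cytosolic and nuclear acetyl-CoA synthetase, which makes acetyl-CoA from acetate. Every animal group had received a Lieber-DeCarli ethanol liquid diet, which supplies alcohol in the food, for 10 days and then 1 ethanol binge, per the labels. Each genotype had 3 libraries, and the genotype label of each sample set its group. The labels do not say that the 3 libraries of a genotype came from separate animals, so the p-values measure the spread between these samples, which may be partly technical. Libraries were made with the VAHTS Universal V6 kit, per the labels' protocols.

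The deposited table holds 16135 genes with 1 FPKM value (fragments scaled to gene length and library total) for each of the 6 libraries, computed by the authors. The submitters' processing notes name the genome build mm10 and the tool DESeq2, without saying what each was used for. The aligner, the counting tool, the annotation and any filter are not given in the sources used here. An FPKM value is a share of a library, so a few abundant genes that take more fragments lower the FPKM of the others. Genes with similar copies, among them Hamp and Hamp2 and the Saa, Orm, Mup, Cyp and haemoglobin families, share sequence, and how their fragments were divided is unknown. Nearly all genes of the table are protein-coding, and none of the mitochondrially encoded genes of the fixed lists is in the table used here.

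Depth was recovered from the values. An FPKM value is a whole fragment count divided by 1 gene length and 1 library total, and a search for whole lengths and totals gave whole counts, within 0.01 of a whole number in every library, for 16108 genes (99.8% of the table). On simulated values the search returned every count of 99.1% of 1133 genes. The implied totals ran from 33717125 to 39474527 fragments per library. Of these totals, 99.2% to 99.4% lay in genes of the table. The lengths recovered for 248 genes equalled their genomic span, as the transcript length of a gene without introns would. A length is the one the authors divided by, and whether it is always that of a transcript was not tested.

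Tests were run on log2(FPKM + 1) for the 9818 genes with a mean of at least 1 FPKM over the 6 libraries. The pseudocount of 1 makes fold changes of low genes smaller than their FPKM ratios. The main test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are ACSS2-HKO minus ACSS2-flox, and ± after a log2 fold change is its standard error. For single genes an exact permutation test over the 20 arrangements of the 6 libraries was added. With 3 libraries against 3 its smallest two-sided p is 0.1.

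Gene lists were written from textbook knowledge before the data were examined, 28 for pathways and 15 for cell types. The 34 lists with at least 5 tested members were tested with camera (limma), which asks whether a list ranks above or below the other genes, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Each was tested again with the correlation estimated from the data and with fry. The genes named in the text follow a rule that was also fixed before the data were examined. It takes Acss2, Acss1, Acss3, Hamp and Hamp2. It takes up to 12 genes per direction past the threshold, or, where none passes, the 8 of smallest p per direction as values. It takes up to 4 members of smallest p of each list with a call, and of the hepcidin, iron and ferroptosis lists in any case. Of the genes it takes, 3 are not reported here. Genes outside the rule are said to be chosen after their values were seen.

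Both test steps were tried on simulated counts of this comparison with 200 genes changed. With the spread observed gene by gene, over 9703 genes, limma called 20.2% of genes changed 2-fold and 70.7% of those changed 4-fold, with 3 unchanged genes called. With a low spread (dispersion 0.01, 9771 genes) it called 100% of both and 14 unchanged genes. Camera called both simulated lists changed 4-fold and 0 of 2 unchanged lists, too few to measure false calls. The genes were simulated independently of each other, so this trial could not show how camera behaves where genes vary together.

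The alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter, a filter at 5 FPKM, other scalings (TPM, trimmed mean of M-values, median ratio, quantile), other variance models, protein-coding genes alone, a minimum log2 fold change of 1, the replicate number as a block, and each library left out in turn. A loess correction for gene length (span 0.5), limma array weights, limma voom on the recovered fragments, leaving out ACSS2-flox replicate 1 and ACSS2-HKO replicate 3 together, the unadjusted threshold, median-ratio scaling for lists, lists without the members of another list, and camera over the KEGG pathways in the deposited table were added after the data were seen. No 2 libraries shared more than 2 identical values among the tested genes, so all 6 were kept as separate libraries. Coordinates are those of the RefSeq annotation of mm10 (GRCm38), matched by gene identifier for 99.5% of genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.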

Results

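Liver transcriptomes were compared between ethanol-fed mice that lack ACSS2 in hepatocytes (ACSS2-HKO, n = 3 libraries) and ethanol-fed floxed controls (ACSS2-flox, n = 3). The FPKM values implied totals of 33717125, 37199061 and 38321306 fragments for ACSS2-flox replicates 1, 2 and 3. They implied 35362997, 35904126 and 39474527 for ACSS2-HKO replicates 1, 2 and 3. ACSS2-flox replicate 1 and ACSS2-HKO replicate 3 stood apart from the other libraries. On log2(FPKM + 1) values the first principal component held 47.2% of the variance and placed ACSS2-flox replicate 1 at -47.7, ACSS2-HKO replicate 3 at 27.6 and the remaining libraries between 2.51 and 8.49. The 20 most abundant genes took 28.6% of fragments in ACSS2-flox replicate 1 and 28.3% in ACSS2-HKO replicate 3, against 24.1% to 25.3% in the other libraries. The median FPKM of tested genes was 5.20 in ACSS2-flox replicate 1 and 6.67 to 7.09 elsewhere. In ACSS2-flox replicate 1 short genes read higher and long genes lower than in the other ACSS2-flox libraries, by a median of 0.28 in the shortest 10% of genes and -0.55 in the longest 10%.

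**Figure D1:**
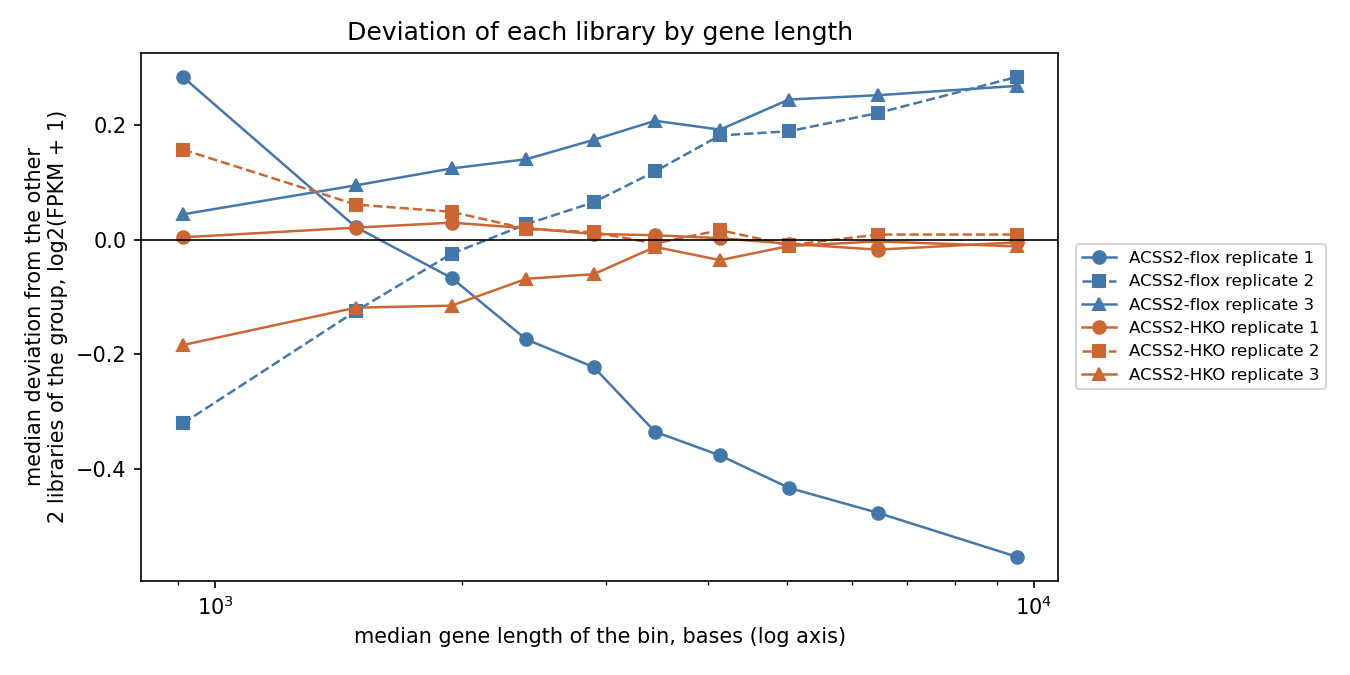
Median deviation of each library from the other 2 libraries of its group, on the log2(FPKM + 1) scale, for 10 bins of the tested genes by gene length (log axis, bases). ACSS2-flox replicate 1 runs from 0.28 in the bin of shortest genes to -0.55 in that of the longest, and it is part of the reference of ACSS2-flox replicates 2 and 3, whose lines slope the other way. The difference of replicates 2 and 3, which leaves replicate 1 out, also followed length (Spearman rho across genes 0.231).

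Acss2 itself (chromosome 2, 155518043 to 155562743) read lower in each ACSS2-HKO library than in any ACSS2-flox library. Its FPKM was 87.8, 61.5 and 58.5 in ACSS2-flox and 50.6, 38.4 and 45.7 in ACSS2-HKO. The means were 69.2 ± 16.1 and 44.9 ± 6.13 FPKM (SD, n = 3), a ratio of 0.648. The log2 fold change was -0.60 ± 0.21, or -0.70 relative to the median of all tested genes, with a limma adjusted p of 0.637. The exact permutation p was 0.1, the smallest that 3 against 3 allows. The value covers the whole gene, so it can keep signal from exons outside the deleted part and from liver cells other than hepatocytes. Without ACSS2-flox replicate 1 the log2 fold change of Acss2 was -0.418. Genes that were not targeted had ratios as low, such as Fads1 (0.584), so the value alone does not show the deletion. Of the paralogs, the mitochondrial enzyme gene Acss1 read 0.13, 0.04 and 0.04 FPKM in ACSS2-flox and a mean of 0.169 ± 0.0438 FPKM (SD, n = 3) in ACSS2-HKO, below the filter. Acss3 read 11.4 ± 1.80 and 9.13 ± 2.66 FPKM, with a log2 fold change of -0.31 ± 0.23 and a limma adjusted p of 0.759, and its fold change ran from -0.511 to -0.149 with single libraries left out.

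The comparison addresses what the loss of hepatocyte ACSS2 does to the ethanol-fed liver, with hepcidin and iron named in the study's title. Transcripts of the hepcidin gene Hamp and of its copy Hamp2 were several-fold lower in ACSS2-HKO liver. Acute phase genes, which hepatocytes secrete into blood during inflammation, were higher as a list, and so were neutrophil and macrophage markers, NRF2 targets and matrix genes. Clock, lipogenesis, xenobiotic metabolism and female-biased liver genes were lower as lists. These calls came from camera with its preset correlation, and all were lost with an estimated correlation and with fry (0 lists each). Every other split of the 6 libraries, 3 against 3, also gave at least 11 camera calls with the preset correlation. No single gene passed the adjusted threshold.

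By limma, 0 of 9818 genes were higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 0.452. At an unadjusted p under 0.05 limma gave 598 higher and 147 lower genes, 745 in all, where chance alone would give 491 on average. That average carries no spread, and the other splits of the 6 libraries, 3 against 3, gave 93 to 560 such genes. With voom on the recovered fragments the counts were 0 and 0 after adjustment, and 345 higher and 299 lower at an unadjusted p under 0.05. The split into higher and lower moved with scaling and with ACSS2-flox replicate 1. The median log2 fold change of all tested genes was 0.10 as deposited and -0.01 after median-ratio scaling. Of the genes at an unadjusted p under 0.05, 80.3% were higher as deposited, 55.1% with median-ratio scaling, 56.0% with trimmed means of M-values, 52.3% with quantile normalization, 50.1% after the gene length correction and 52.2% without ACSS2-flox replicate 1. Without ACSS2-HKO replicate 3 the counts were 282 higher and 74 lower. Without both distant libraries they were 527 and 371, with 0 genes past the adjusted threshold. The groups did not overlap for 1521 genes, 15.5% of those tested against an average of 10% by chance, again without a spread. As deposited, 1232 of these were higher and 289 lower in ACSS2-HKO, and this division was not counted with other scalings.

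Hamp, which encodes the iron hormone hepcidin (chromosome 7, 30942368 to 30944029), read 2950, 1241 and 897 FPKM in ACSS2-flox and 117, 311 and 567 FPKM in ACSS2-HKO. The means of 1696 ± 1099 and 332 ± 225 FPKM (SD, n = 3) differed 5.11-fold. Its log2 fold change was -2.43 ± 0.60 with a limma adjusted p of 0.554. The neighbouring copy Hamp2 (chromosome 7, 30922372 to 30924181) read 2619, 733 and 543 FPKM in ACSS2-flox and 99.5, 145 and 63.5 FPKM in ACSS2-HKO, 12.6-fold lower by means. Its log2 fold change was -3.37 ± 0.56 and its limma adjusted p 0.452. Neither gene overlapped between the groups (exact permutation p = 0.1 for each, the smallest possible). The highest value of both was that of ACSS2-flox replicate 1, and without it the log2 fold changes were -1.94 and -2.69. Hamp read -1.823 without ACSS2-HKO replicate 1, the lowest in size with 1 library left out. The copies share sequence, so the division of fragments between them is uncertain, though both were lower. Whether the product of Hamp2 acts on iron as hepcidin does was not examined.

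**Figure D2:**
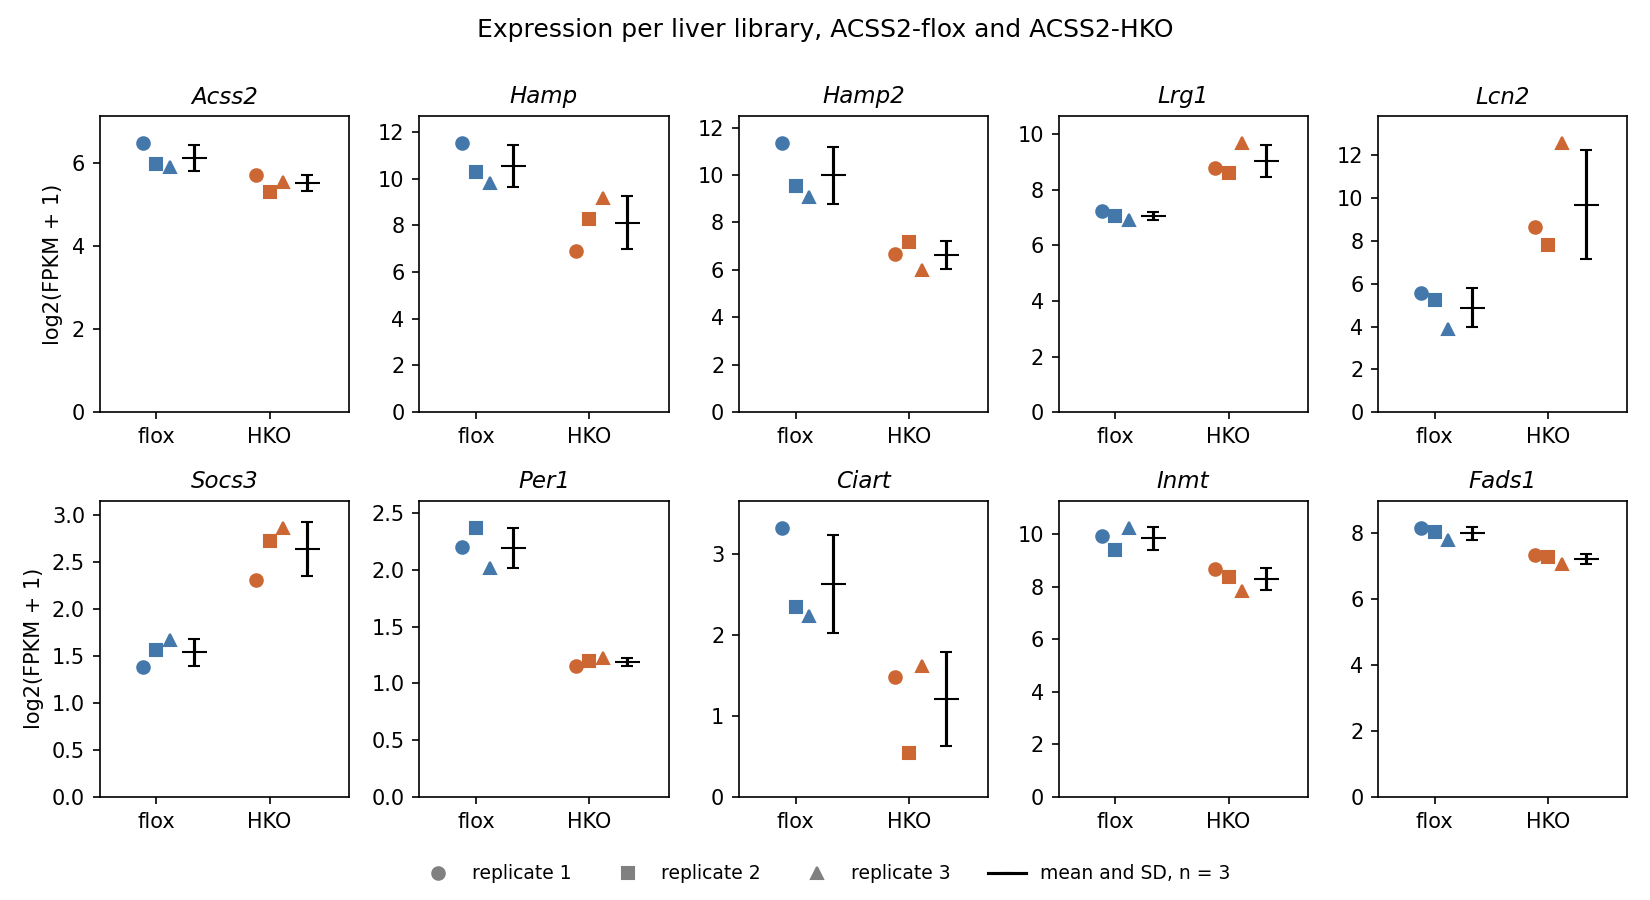
Expression of 10 genes in each liver library on the log2(FPKM + 1) scale, with symbols for the 3 replicates of ACSS2-flox (blue) and ACSS2-HKO (orange) and bars for the mean and SD (n = 3). Every gene shown has groups that do not overlap, as have 15.5% of all tested genes. Apart from Acss2, Hamp and Hamp2, the genes were named for a small p, which favours such groups. Among those shown are Acss2 (log2 fold change -0.60), Hamp (-2.43), Hamp2 (-3.37) and Lcn2 (4.79), and no gene shown passed the limma adjusted threshold.

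Of the other genes on the hepcidin regulation list, 24 tested in all, none had a log2 fold change beyond 0.361 in size. The transcription factor gene Cebpa read -0.36 ± 0.17 and the iron sensor gene Hfe 0.36 ± 0.18. No member passed adjustment over all genes by limma, and 2 of the 24, Hamp and Hamp2, were lower when adjusted over the list alone. The list had no call (camera adjusted p = 0.209, and adjusted p = 0.587 with an estimated correlation). Its median log2 fold change was 0.11 and its mean -0.17, and camera placed it lower, so the signs differed. Hamp (-2.43) and Hamp2 (-3.37) are members themselves, and the list was not tested without them. Its placement is therefore no separate sign of a change in the other hepcidin regulators. The median ran from -0.079 to 0.213 with single libraries left out. The call appeared without both distant libraries (camera adjusted p = 0.0140) and with array weights (0.0318), among camera alternatives that ran from 0.0140 to 0.587. Fry gave an adjusted p of 0.967.

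Genes for iron uptake, storage and export were higher as a list, with 27 of 34 tested members positive and a median log2 fold change of 0.31, or 0.21 above that of all genes (camera adjusted p = 0.00601, and adjusted p = 0.411 with an estimated correlation). No member passed limma over all genes or adjusted over the list alone. Lcn2, which encodes the siderophore-binding lipocalin 2, read 45.9, 36.8 and 13.6 FPKM in ACSS2-flox and 403, 222 and 6099 FPKM in ACSS2-HKO. The transferrin receptor gene Tfrc read 2.34 ± 1.18 and 5.49 ± 1.38 FPKM (SD, n = 3), a log2 fold change of 0.996 ± 0.284. The haem transporter gene Slc48a1 and the haemopexin receptor gene Lrp1 had log2 fold changes of 0.64 ± 0.19 and 0.63 ± 0.19. The list shares 5 genes with the acute phase list (Cp, Hp, Hpx, Lcn2 and Steap4), and without them the median of the other 29 was 0.24 and the camera adjusted p 0.143. Without ACSS2-flox replicate 3 the camera adjusted p was 0.0569 although the median was larger (0.373), and with single libraries left out the median ran from 0.176 to 0.373. Over all camera alternatives the adjusted p ran from 6.30e-04 to 0.411, and fry gave 0.505.

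The ferroptosis lists had no call. Ferroptosis is an iron-dependent cell death driven by lipid peroxides. The 19 drivers tested had a median log2 fold change of -0.06 (camera adjusted p = 0.280, and adjusted p = 0.554 with an estimated correlation), with Tfrc as the member of smallest p. Lpcat3, Hmgb1 and Ncoa4 read -0.35 ± 0.25, -0.24 ± 0.27 and 0.32 ± 0.35 on the log2 scale, and with single libraries left out -0.532 to -0.119, -0.466 to 0.052 and -0.138 to 0.572. The 27 suppressors had a median of 0.10, or -0.004 relative to all genes, and camera placed them lower (adjusted p = 0.327, and adjusted p = 0.600 with an estimated correlation). Of these, Nqo1 and Mt1 read 0.76 ± 0.18 and 0.73 ± 0.31, and the desaturase genes Fads2 and Scd1 read -0.79 ± 0.26 and -1.34 ± 0.52. Without ACSS2-HKO replicate 1, Mt1 read 0.449 and Scd1 -0.875. In both lists 0 members passed limma over all genes and 0 passed when adjusted over the list alone. The sign of both medians turned with single libraries left out. They ran from -0.084 to 0.105 for drivers and from -0.043 to 0.163 for suppressors.

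Acute phase genes were higher as a list in ACSS2-HKO. Of 34 tested members 33 had positive log2 fold changes, with a median of 1.02, or 0.92 above that of all genes (camera adjusted p = 7.37e-14, and adjusted p = 0.411 with an estimated correlation). No member passed limma over all genes, and 13 passed when adjusted over the list alone, 12 higher and 1 lower. Lrg1, which encodes a leucine-rich plasma glycoprotein, had the smallest p of all genes. It read 133 ± 14.6 FPKM in ACSS2-flox and 550 ± 237 FPKM in ACSS2-HKO (SD, n = 3), a log2 fold change of 1.97 ± 0.29 (limma adjusted p = 0.452). Socs3, the feedback inhibitor of cytokine signalling, read 1.91 ± 0.283 and 5.29 ± 1.19 FPKM, and the orosomucoid gene Orm3 read 2.39 ± 0.153 FPKM in ACSS2-flox and 11.4, 8.36 and 46.3 FPKM in ACSS2-HKO. The median of the list relative to the ACSS2-flox mean was 0.60, 0.75 and 1.62 in ACSS2-HKO replicates 1, 2 and 3, and between -0.05 and 0.04 in the ACSS2-flox libraries. Without ACSS2-HKO replicate 3, the library with the highest values, the list had a median of 0.71 and kept its camera call. Inflammatory cytokine and chemokine genes were also higher as a list (17 of 19 positive, median 0.87, camera adjusted p = 8.02e-04, and adjusted p = 0.511 with an estimated correlation). Cxcl13, Cxcl1, Il1b and Icam1 had log2 fold changes of 1.38 ± 0.32, 2.67 ± 0.74, 0.92 ± 0.33 and 1.16 ± 0.42, and 1 member passed limma when adjusted over the list alone. Cxcl1, Il1b and Icam1 read 1.635, 0.552 and 0.607 without ACSS2-HKO replicate 3. That list had a median of 0.17 and a camera adjusted p of 0.0637 without ACSS2-HKO replicate 3, and a median of 0.78 and an adjusted p of 0.0861 without ACSS2-flox replicate 3.

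Markers of myeloid cells were higher in ACSS2-HKO, beside the acute phase genes. Of the 15 neutrophil markers present, 6 were tested, and a rise in ACSS2-HKO can itself lift a marker past the filter. All 6 were positive, with a median log2 fold change of 2.53 (camera adjusted p = 2.52e-06, and adjusted p = 0.411 with an estimated correlation). Of these, Lcn2 is also on the acute phase list. Without it the other 5 had a median of 2.48 and a camera adjusted p of 5.40e-05. The 9 markers below the filter were positive too, with a median of 0.411. The median of the tested markers was 1.40, 1.75 and 4.30 in ACSS2-HKO replicates 1, 2 and 3. The calprotectin genes S100a8 and S100a9 read 4.69 ± 1.496 and 6.79 ± 3.30 FPKM in ACSS2-flox (SD, n = 3). In ACSS2-HKO, S100a8 read 16.6, 20.8 and 138 FPKM and S100a9 15, 27.9 and 177 FPKM. Retnlg read 0.655 ± 0.218 FPKM in ACSS2-flox and 5.21, 3.76 and 25.04 FPKM in ACSS2-HKO. By limma 0 markers passed over all genes and 4 passed when adjusted over the list alone. All 16 tested Kupffer cell and macrophage markers were positive as well (median 0.88, camera adjusted p = 1.79e-08, and adjusted p = 0.411 with an estimated correlation), with 0 past limma in either adjustment. The complement component genes C1qc and C1qb had log2 fold changes of 0.98 ± 0.32 and 0.94 ± 0.32, and Marco and Cd9 ones of 1.92 ± 0.62 and 0.83 ± 0.21. S100a8, S100a9, C1qc, C1qb and Marco had log2 fold changes of 1.813, 1.572, 0.609, 0.547 and 1.231 without ACSS2-HKO replicate 3. Both lists kept their camera calls without each library in turn, with lowest medians of 1.648 for neutrophils and 0.506 for macrophages, both without ACSS2-HKO replicate 3.

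NRF2 antioxidant targets and matrix genes were higher as lists too. Of 28 NRF2 targets 24 were positive, with a median log2 fold change of 0.46, or 0.36 above that of all genes (camera adjusted p = 0.00223, and adjusted p = 0.411 with an estimated correlation). By limma 0 members passed over all genes and 2, Cbr3 and Nqo1, were higher when adjusted over the list alone. The carbonyl reductase gene Cbr3 read 0.410 ± 0.171 and 3.46 ± 1.89 FPKM and the quinone reductase gene Nqo1 read 7.04 ± 0.988 and 12.6 ± 1.27 FPKM (SD, n = 3). Gstm3 and the transporter gene Abcc3 had log2 fold changes of 1.195 ± 0.38 and 0.78 ± 0.27. ACSS2-flox replicate 1 had the lowest list median, -0.39, and without it the median log2 fold change was 0.239. Of 18 extracellular matrix genes 17 were positive, with a median of 0.54 (camera adjusted p = 1.01e-04, and adjusted p = 0.411 with an estimated correlation) and 0 members past limma in either adjustment. The collagen genes Col1a1, Col3a1 and Col1a2 had log2 fold changes of 0.89 ± 0.25, 0.75 ± 0.27 and 0.70 ± 0.28, and the membrane metalloproteinase gene Mmp14 one of 0.68 ± 0.19. Col3a1 and Col1a2 read 0.478 and 0.461 without ACSS2-HKO replicate 3. The median of the matrix list was 0.304 without ACSS2-flox replicate 1, and 0.17 with a camera adjusted p of 0.105 without both distant libraries.

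The circadian clock list was lower in ACSS2-HKO, with 15 of 19 tested members negative and a median log2 fold change of -0.44, or -0.54 relative to all genes (camera adjusted p = 5.91e-09, and adjusted p = 0.33 with an estimated correlation). Over all genes 0 members passed limma, and 2, Per1 and Ciart, were lower when adjusted over the list alone. The clock repressor gene Per1 read 3.60 ± 0.566 FPKM in ACSS2-flox and 1.28 ± 0.0567 FPKM in ACSS2-HKO (SD, n = 3), a log2 fold change of -1.007 ± 0.17 (limma adjusted p = 0.452). Ciart, Usp2 and the clock output gene Dbp read -1.42 ± 0.37, -0.92 ± 0.27 and -1.09 ± 0.37 on the log2 scale, and Dbp -0.642 without ACSS2-flox replicate 1. Fry's test for change in either direction gave the clock list an adjusted p of 0.0182, and its test for change in 1 direction an adjusted p of 0.505. The list kept its camera call without each library in turn, while its median ran from -0.488 to -0.2, the latter without ACSS2-flox replicate 3.

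Genes of lipid and drug metabolism were lower as lists. Of 25 lipogenesis genes 20 were negative, with a median log2 fold change of -0.44 (camera adjusted p = 7.22e-08, and adjusted p = 0.411 with an estimated correlation). The fatty acid desaturase genes Fads1 and Fads2 read 257 ± 34.0 and 489 ± 76.2 FPKM in ACSS2-flox, and 150 ± 15.5 and 291 ± 95.7 FPKM in ACSS2-HKO (SD, n = 3). Scd1 and Elovl5 had log2 fold changes of -1.34 ± 0.52 and -0.69 ± 0.30. Of 32 xenobiotic metabolism genes 25 were negative (median -0.28, camera adjusted p = 2.42e-06, and adjusted p = 0.411 with an estimated correlation), with Nr1i3, which encodes the receptor CAR, at -0.53 ± 0.22, Sult1d1 at -0.53 ± 0.23, Gstt1 at -0.56 ± 0.26 and Cyp3a13 at 0.44 ± 0.19. Of 29 female-biased liver genes 24 were negative (median -0.39, camera adjusted p = 7.22e-08, and adjusted p = 0.411 with an estimated correlation). Hao2 and Sult3a1 read -1.68 ± 0.53 and -1.48 ± 0.55 on the log2 scale, and Prom1 read 1.005 ± 0.27. Without ACSS2-HKO replicate 3, Sult1d1, Gstt1, Hao2 and Sult3a1 read -0.315, -0.336, -0.979 and -0.959. Without ACSS2-flox replicate 1, Elovl5 and Nr1i3 read -0.453 and -0.333, and Scd1 read -0.875 without ACSS2-HKO replicate 1. In these 3 lists 0 members passed limma over all genes, and only Hamp2 of the female-biased list passed when adjusted over the list alone. The median of the female-biased list was -0.02, -0.26 and -0.85 in ACSS2-HKO replicates 1, 2 and 3. With single libraries left out the median ran from -0.685 to -0.181 for lipogenesis, from -0.391 to -0.083 for xenobiotic metabolism and from -0.597 to -0.156 for the female-biased list. Without both distant libraries the xenobiotic and female-biased lists had camera adjusted p values of 0.331 and 0.563.

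**Figure D3:**
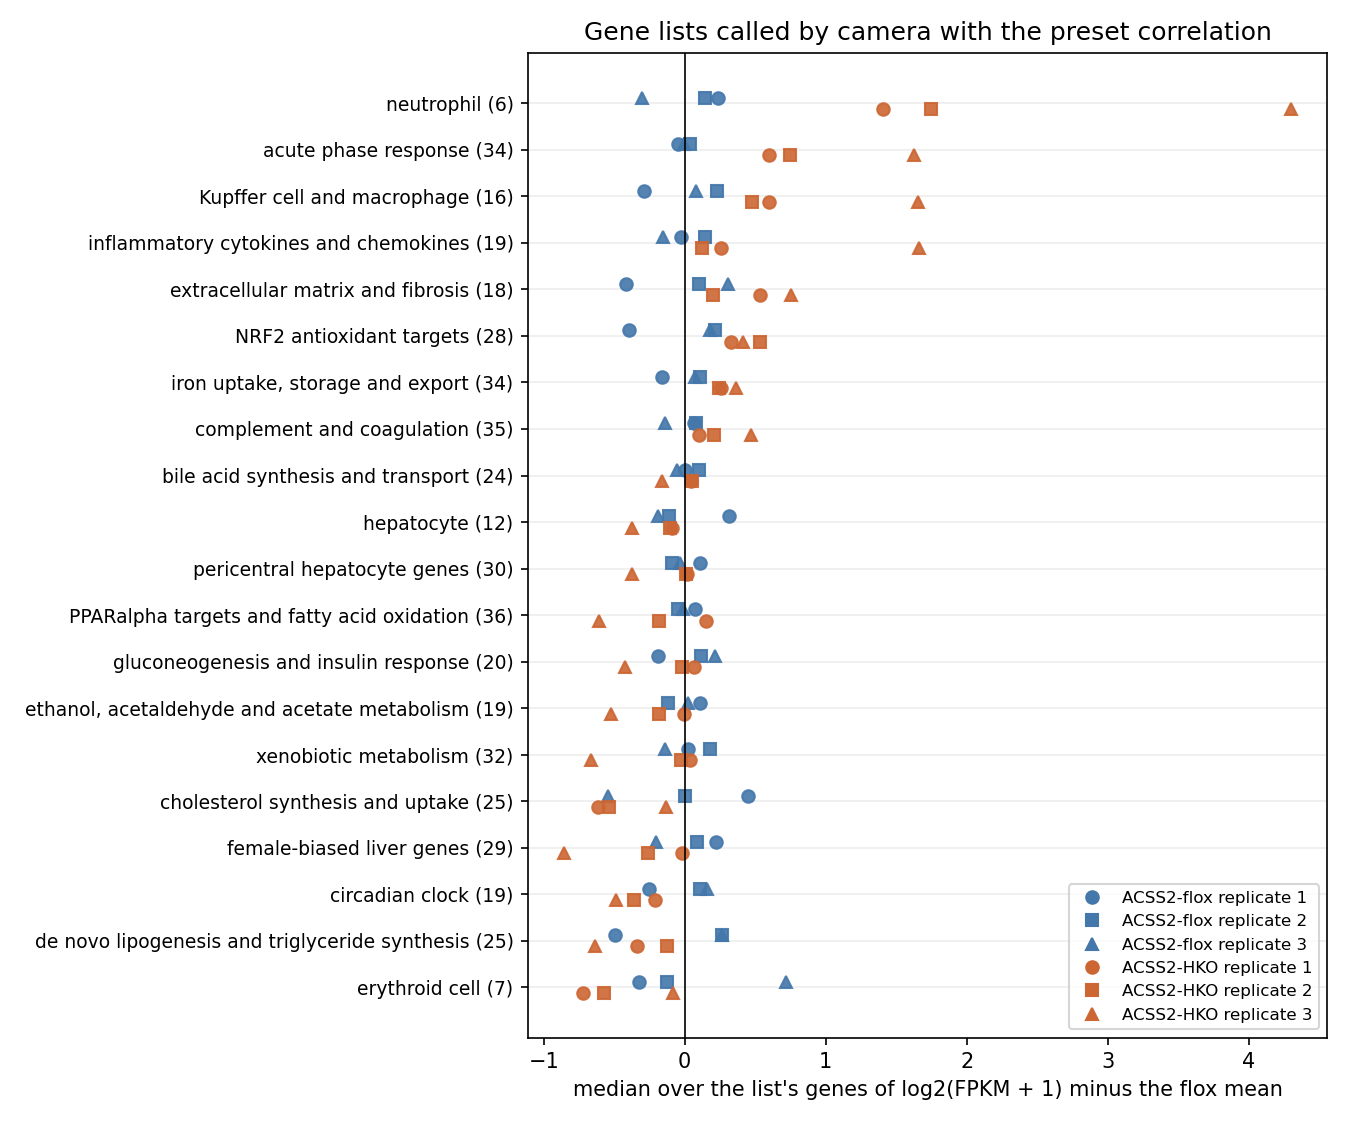
Median over each list's tested genes (number in brackets) of log2(FPKM + 1) minus the ACSS2-flox mean, per library, for the 20 lists called by camera with the preset correlation. In the acute phase list the ACSS2-HKO libraries sit at 0.60, 0.75 and 1.62 and the ACSS2-flox libraries between -0.05 and 0.04, while ACSS2-HKO replicate 3 holds the highest ACSS2-HKO values of the neutrophil and macrophage lists.

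The remaining calls among lower lists were lost without at least 1 single library. Cholesterol synthesis genes were negative in 22 of 25 cases (median -0.37, camera adjusted p = 9.49e-09, and adjusted p = 0.411 with an estimated correlation), with Fdft1 at -0.83 ± 0.28, Stard4 at -0.71 ± 0.22 and Sc5d at -0.63 ± 0.22. Without ACSS2-flox replicate 1, in which the list median was 0.45, that list had a median of -0.121 and a camera adjusted p of 0.0918, and Fdft1 read -0.519. Targets of PPARα in fatty acid oxidation were negative in 29 of 36 cases (median -0.23, camera adjusted p = 4.53e-07, and adjusted p = 0.411 with an estimated correlation), with Fabp1 at -0.96 ± 0.40, Acaa1b at -0.82 ± 0.33, Acot4 at -0.55 ± 0.19 and Slc27a2 at -0.53 ± 0.24. Fabp1 and Acaa1b read -0.602 and -0.457 without ACSS2-HKO replicate 3. The median was -0.024 without that library (camera adjusted p = 0.0642) and 0.043 without both distant libraries (0.927). Ethanol and acetate metabolism genes were negative in 14 of 19 cases (median -0.26, camera adjusted p = 3.10e-04, and adjusted p = 0.411 with an estimated correlation). The median was -0.164 without ACSS2-flox replicate 1 (camera adjusted p = 0.0580) and -0.042 without both distant libraries (0.368). It ran from -0.343 to -0.073 with single libraries left out. The ethanol-oxidising Cyp2e1 read 3610 ± 1276 and 2166 ± 1210 FPKM (SD, n = 3), Sirt3 had a log2 fold change of -0.40 ± 0.21, and Aldh1a7 and Aldh1a1 read 0.38 ± 0.20 and 0.31 ± 0.18. Without ACSS2-HKO replicate 3 the log2 fold changes of Cyp2e1 and Sirt3 were -0.406 and -0.229. The joint list of gluconeogenesis and insulin response genes had a median of -0.25 (camera adjusted p = 0.00301, and adjusted p = 0.411 with an estimated correlation). Of its members, Gys2 read -0.64 ± 0.22, Igfbp2 -0.70 ± 0.29, Ppp1r3g -1.58 ± 0.69 and Ppp1r3c 1.18 ± 0.36 on the log2 scale. Without ACSS2-HKO replicate 3 the median was -0.054 (camera adjusted p = 0.108) and Igfbp2 read -0.4, and without ACSS2-flox replicate 1 Ppp1r3g read -2.406. With single libraries left out the median of this list ran from -0.337 to -0.002. In these 4 lists 0 members passed limma over all genes or when adjusted over the list alone.

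Pericentral genes, which mark hepatocytes around the central vein, had a median of -0.19 (camera adjusted p = 0.00109, and adjusted p = 0.411 with an estimated correlation). It was -0.126 without ACSS2-flox replicate 1 (camera adjusted p = 0.397) and -0.017 without ACSS2-HKO replicate 3 (0.0627). Oat, Lhpp and Rgn read -0.64 ± 0.19, -0.49 ± 0.19 and -0.96 ± 0.40 on the log2 scale, while Slc13a3 read 0.81 ± 0.19, and Rgn read -0.6 without ACSS2-flox replicate 1. Hepatocyte markers had a median of -0.15 (camera adjusted p = 0.0227, and adjusted p = 0.411 with an estimated correlation), and of -0.059 without ACSS2-flox replicate 1 (0.717) and -0.065 without ACSS2-HKO replicate 3 (0.0637), with Apoa2 at -0.75 ± 0.39, Ttr at -0.59 ± 0.33, Apob at 0.38 ± 0.29 and Fgb at 0.37 ± 0.29. Without ACSS2-flox replicate 1, Apoa2, Ttr and Apob read -0.331, -0.302 and 0.057, and with single libraries left out Fgb ran from 0.2 to 0.603. Erythroid markers had a median of -0.44 (camera adjusted p = 0.00288, and adjusted p = 0.411 with an estimated correlation), and of -0.023 without ACSS2-flox replicate 3 (0.133), with Hba-a1 and Hba-a2 at -0.60 ± 0.31 and -0.63 ± 0.33 and Bpgm at 0.39 ± 0.24. Without ACSS2-flox replicate 3 the haemoglobin genes read -0.238 and -0.243, and with single libraries left out Bpgm ran from 0.226 to 0.611. With other single libraries left out the list medians reached -0.293 for pericentral, -0.29 for hepatocyte and -0.728 for erythroid genes. Bile acid genes had a median of 0.003, a mean of -0.04 and a lower call (camera adjusted p = 0.0443, and adjusted p = 0.411 with an estimated correlation), so the median and the call differed in sign. Cyp7a1, the rate-limiting enzyme gene of bile acid synthesis, read 63.2, 135 and 40.6 FPKM in ACSS2-flox and 25.7 ± 9.40 FPKM (SD, n = 3) in ACSS2-HKO, and Slco1a4 and Abcc4 read -0.96 ± 0.27 and 0.87 ± 0.38 on the log2 scale, and Abcc4 0.455 without ACSS2-flox replicate 1. The bile acid call was absent without ACSS2-flox replicate 1 (camera adjusted p = 0.857), ACSS2-flox replicate 2 (0.121), ACSS2-HKO replicate 2 (0.0969) or ACSS2-HKO replicate 3 (0.0718). Complement and coagulation genes were higher (28 of 35 positive, median 0.27, camera adjusted p = 0.0173, and adjusted p = 0.587 with an estimated correlation). The median was 0.208 without ACSS2-flox replicate 3 (camera adjusted p = 0.925) and 0.15 without ACSS2-HKO replicate 3 (0.175). C8a, Hc and C8b read 1.04 ± 0.31, 0.65 ± 0.22 and 0.76 ± 0.26 on the log2 scale, and C8b 0.485 without ACSS2-HKO replicate 3. None of these members passed limma over all genes or when adjusted over the list alone.

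The remaining genes of smallest p are given as values, since none passed the limma adjusted threshold. The interferon-inducible Ifi27l2b read 6.69 ± 0.770 and 29.4 ± 11.7 FPKM (SD, n = 3), the endoplasmic reticulum gene Sdf2l1 read 8.31 ± 2.66 and 27.3 ± 6.30 FPKM, and Ly6d read 9.91 ± 2.98 and 84.4 ± 49.0 FPKM. Slc41a2 and Syne4 had log2 fold changes of 1.40 ± 0.24 and 1.202 ± 0.219. The methyltransferase gene Inmt read 947 ± 274 and 318 ± 88.9 FPKM, and the uridine phosphorylase gene Upp2 read 50.9 ± 29.2 and 11.9 ± 4.82 FPKM. The sulfotransferase genes Sult1c2 and Sult2a8 had log2 fold changes of -0.95 ± 0.18 and -1.68 ± 0.35, Coq10b one of -1.03 ± 0.20 and Serpinb1a one of -0.86 ± 0.17. Without ACSS2-HKO replicate 2, 3 genes passed limma, all higher, namely Ly6d, Ifi27l2b and Smpd3 (adjusted p = 0.0297 for each). Smpd3 was named after its values were seen.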

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

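The unadjusted counts, array weights, voom, the gene length correction, the fits without both distant libraries, median-ratio scaling for lists, and the genes Mup2 and Smpd3 were chosen after the result was seen. The count test planned for the case that whole reads could be recovered was not run although they could, because a count test was held unfit for deposited FPKM values, and voom was run in its place. The log2 fold changes of Acss2 (-0.76 to -0.42) and Hamp (-2.95 to -1.82) kept their sign and stayed short of the limma adjusted threshold in all 22 alternatives (adjusted p 0.347 to 0.9995 and 0.136 to 0.762). Genes past the adjusted threshold numbered 0 higher and 0 lower in every alternative except 2. The replicate block gave 1 higher (Ifi27l2b, adjusted p = 0.0479) and 3 lower (Hamp2, Mup2 and Upp2, adjusted p = 0.0462 each). Leaving out each library in turn gave 0 to 3 higher and 0 lower, with the 3 (Ly6d, Ifi27l2b and Smpd3) without ACSS2-HKO replicate 2. Limma adjusted p values of Ifi27l2b and Ly6d ran from 0.0297 to 0.760, of Hamp2 from 0.0462 to 0.760 and of Upp2 from 0.0462 to 0.9995. Same-numbered libraries did not deviate together (correlations across genes of 0.013, 0.003 and -0.063), so the numbers mark no pairs.

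At an unadjusted p under 0.05, limma gave 598 higher and 147 lower genes. Higher genes numbered 917 with no filter and 311 at a filter of 5 FPKM, where more and fewer genes are tested. Higher and lower genes numbered 381 and 299 with trimmed means, 371 and 302 with the median ratio, 391 and 357 with quantiles, 394 and 393 after the length correction, 345 and 299 with voom, and 78 and 40 at a minimum log2 fold change of 1. Lower genes numbered 382 with array weights and 371 without both distant libraries. With single libraries left out the counts ran from 282 (without ACSS2-HKO replicate 3) to 579 higher, and from 74 (without ACSS2-HKO replicate 3) to 460 (without ACSS2-flox replicate 1) lower. The cause was not tested.

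Camera called 8 lists higher and 12 lower. With an estimated correlation and with fry the counts were 0 and 0. Leaving out single libraries gave 6 to 10 higher and 7 to 12 lower, and without both distant libraries 7 and 7. Of the 20 called lists, 9 kept the call without each library in turn. Over all alternatives the single lists lost a call with their direction kept 84 times, gained 1 on 2 occasions and read the same 281 times. The direction of a list is the side on which the test placed it, which can differ from the sign of its median. PPARα targets without both distant libraries (median 0.043) were still placed lower. Direction turned for 2 genes and 4 lists, and 2 of these lists, pericentral genes and hepatocyte markers, were among the 12 called lower and lost those calls too. Hmgb1 read -0.466 to 0.052 with single libraries left out, 0.045 with array weights and 0.112 without both distant libraries. Ncoa4 read -0.138 to 0.572, -0.087 and -0.15 in the same fits. Without both distant libraries camera placed the pericentral (median -0.022) and hepatocyte (0.039) lists higher. Ferroptosis suppressors turned with quantiles (0.034) and with fry (0.095), and drivers with fry (-0.063). The cause was not tested. Depth limits low genes such as Cbr3, with 11 to 259 fragments per library, more than Hamp with 1691 to 40476.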

Other observations

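The KEGG pathways, the member genes Pdia6, Dnajb11, Cd36, Fabp4, Ces1d, Mup12, Mup3, Krt8, Krt18, Muc1, Jchain, Car3, Id1, Smad6, Smad7, Atoh8, Arntl and Npas2, the tests of hepatocyte-made acute phase genes, of hepcidin without ACSS2-flox replicate 1 of the distance of that library after the length correction and of its short and long genes, and the split count of unadjusted genes were chosen after the results were seen. The integrated and endoplasmic reticulum stress list had no call (29 tested, camera adjusted p = 0.209). Adjusted over the list alone by limma, 3 members were higher in ACSS2-HKO, namely Sdf2l1 (log2 fold change 1.62), Pdia6 (0.91) and Dnajb11 (0.72), against 0 over all genes. Lipid droplet genes had no call either (23 tested, camera adjusted p = 0.988). Adjusted over that list alone, the fatty acid carrier genes Cd36 (1.08) and Fabp4 (1.06) were higher and the carboxylesterase gene Ces1d (-1.001) was lower. Among 17 male-biased genes (camera adjusted p = 0.0676), the urinary protein genes Mup12 (-1.08) and Mup3 (-1.79) were lower and C8a (1.04) was higher when adjusted over the list alone. Mup genes share sequence, so their single values are uncertain.

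Other lists had no camera call. These were the interferon response (31 tested, median log2 fold change 0.24, adjusted p = 0.280), proliferation (24, 0.28, 0.224), immediate early genes (19, 0.14, 0.904), periportal genes (31, 0.05, 0.449), cysteine and glutathione metabolism (24, 0.05, 0.448), T and NK cells (7, 0.17, 0.616), sinusoidal endothelial cells (14, 0.18, 0.862) and stellate cells (14, 0.23, 0.224). Camera, which sets a list against all other genes, placed the immediate early, periportal and cysteine lists lower although their medians were above 0. Lists with under 5 tested members were not tested by camera. Of these, the keratin genes Krt8 and Krt18 (0.85 and 0.68), on the gallbladder and mesothelium list but also made by hepatocytes, were both higher when adjusted over the list alone. So were 1 of 3 cholangiocyte markers (Muc1, 0.72) and 1 of 3 B and plasma cell markers (Jchain, 1.29). Of 2 adipocyte markers Fabp4 was higher and Car3 (-1.45) lower. With only 2 or 3 tested members this adjustment is close to an unadjusted p, and nothing was adjusted across the lists. None of these markers passed limma over all genes. The platelet, pancreas, intestine and muscle lists had 1, 1, 2 and 1 tested members and 0 past adjustment over the list alone, and the mitochondrially encoded list had 0 tested.

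Camera over 308 KEGG pathways with 10 to 300 tested members called 65 higher and 40 lower with the preset correlation and 0 with an estimated one. Oxidative phosphorylation was lower (103 genes, median log2 fold change -0.15, camera adjusted p = 1.20e-07), as were steroid hormone biosynthesis (59 genes, -0.21, 1.20e-07) and peroxisome (79 genes, -0.12, 7.46e-06). Lysosome was higher (107 genes, 0.28, 2.91e-05). With an estimated correlation the camera adjusted p of each was 0.961. After the length correction the 4 kept their calls (camera adjusted p of 6.05e-06 to 1.20e-04). Without both distant libraries 1 of the 65 higher pathways and 0 of the 40 lower ones kept a call. The 1 was Staphylococcus aureus infection (39 genes, median 0.65, camera adjusted p = 7.74e-06, and 0.00198 without both libraries). Ribosome, called lower (130 genes, 0.00887), was called higher there (0.00198). There oxidative phosphorylation lay on the higher side (camera adjusted p = 0.942), and lysosome, steroid hormone biosynthesis and peroxisome had adjusted p values of 0.0561, 0.505 and 0.719. With all libraries and the preset correlation, glycolysis and gluconeogenesis had no call (48 genes, median 0.094, camera adjusted p = 0.555).

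ACSS2-flox replicate 1 stood apart from the other ACSS2-flox libraries. A few genes taking most of the counts would move all other genes the same way, yet against ACSS2-flox replicate 3 its median difference was 0.169 in the shortest 10% of genes (95% resampling interval over genes 0.131 to 0.208) and -0.556 in the longest, which argues against that explanation as the whole distance. The planned SD ratio after median-ratio scaling (1.549, against 1.516 as deposited) decides nothing, as 1 factor per library could not have brought it down to the level of the others. Its deviation followed gene length (Spearman rho across genes -0.422), but length is not the whole distance, because the SD of its deviations was still 1.453 times the larger SD of the other ACSS2-flox libraries (1.42 to 1.49) after the length correction. Whether the length trend is a property of this library alone cannot be told apart, since ACSS2-flox replicate 2, whose reference includes replicate 1, had a rho of 0.443, and the difference of replicates 2 and 3, free of replicate 1, one of 0.231, and no biological explanation was tested for a single library.

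Acute phase genes were higher in ACSS2-HKO, most of all in ACSS2-HKO replicate 3. That library alone does not account for the list, whose median log2 fold change was 0.71 without it. Whether neutrophils or blood left in the tissue account for part of the list could not be decided. The 11 acute phase genes made by hepatocytes ran from 0.37 (Fgb) to 1.97 (Lrg1) with a median log2 fold change of 1.011, with 0.55, 0.83 and 1.7 in the ACSS2-HKO libraries and -0.13 to 0.02 in the ACSS2-flox libraries. They were picked from a list already seen to be higher, so they are no separate test. Other cells may make some of them too. An effect of the loss of ACSS2, the difference the design names, stays open as untested, and so does a condition shared by these animals for other reasons, since the labels give no batch or housing.

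Hamp and Hamp2 were lower in ACSS2-HKO although hepcidin is itself induced in inflammation, in which acute phase genes are higher. In ACSS2-flox replicate 1 the shortest genes read higher than in the other ACSS2-flox libraries, by a median of 0.28. The length correction removes only such an average trend, so it could not have removed a difference of this size and decides nothing. After it the mean log2 fold change of Hamp and Hamp2 was -2.9. Without ACSS2-flox replicate 1 that mean was -2.312, so neither the high values of that library alone nor a length trend in it alone accounts for the difference. Lower BMP-SMAD signalling, the main inducer of hepcidin, would lower its other targets. Id1, Smad6, Smad7 and Atoh8 had log2 fold changes of -0.24, 0.27, -0.08 and -0.07, with a median of -0.076. That median lay on the side set beforehand as counting against lower BMP-SMAD signalling. The genes go both ways within their spread, however, so this explanation stays open.

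The lower clock list may reflect a different phase of the clock at tissue collection, from time of day or of feeding, rather than a weaker clock. A phase shift would part genes that peak at different times. Of 5 genes set against the Per and output genes, 3 were tested, the activator gene Clock (0.501) and the repressor genes Cry1 (-0.23) and Nfil3 (0.447), which went both ways. Their median log2 fold change was 0.45 against -0.49 for the 9 Per and output genes, a difference of 0.936. That is past the level set beforehand for a phase shift. Taken per library, the gap differed between the groups by 0.763 with a standard error of 0.515, and ACSS2-flox replicate 1 had the lowest value (-0.91), so the test leaves the hypothesis open. The activator genes Arntl and Npas2 lay below the filter. Arntl read 0.05, 0.08 and 0.02 FPKM in ACSS2-flox and 0.21, 0.15 and 0.16 FPKM in ACSS2-HKO, and Npas2 read 0.03, 0.09 and 0.06 FPKM against 0.10, 0.14 and 0.03 FPKM.

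The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. For genes past the limma adjusted threshold the real split gave 0 and the highest other split 0, so all 10 gave as many. For genes at an unadjusted p under 0.05 the real split gave 745 and the highest other 560, so 1 split gave as many. For lists with a camera call the real split gave 20 and the highest other 20, the split that joined ACSS2-flox replicates 1 and 2 with ACSS2-HKO replicate 1, so 2 splits gave as many. Every other split gave at least 11 lists, so camera calls with the preset correlation also arise in splits that mix the genotypes.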
